A study of Mus musculus with 3 samples.

How the data were processed

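Gene expression was measured in pooled retinae of C57 mice on 3 Affymetrix whole-transcript GeneChip arrays, 1 array per group. Per the labels' protocols, an agent was injected into the vitreous of the eye, total RNA was extracted with TRIZOL, its integrity was checked on a Bioanalyzer, and biotin-labelled cDNA was hybridised. Each array held RNA pooled from 5 to 6 retinae. The groups were AP, named by the labels as the control and taken 2 hr after injection, cavtratin, taken 2 hr after injection, and Cav1-shRNA, taken 2 days after injection. The labels do not spell out AP.

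The deposited values were used as the authors gave them, and they were read as log2 expression per probe set. The log base, the summarisation and the normalization are not given in the sources used here, and log2 was inferred from the range of the values. The 3 arrays had close to one shared distribution of values, with sorted columns that differed by at most 0.209. The table held 41345 probe sets. A platform annotation, which can be old, gave 1 gene symbol to 23521 of them and several symbols to 1814, and 16010 were not listed in it. Of the probe sets with 1 symbol, 23328 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols had to be updated. Probe sets with several symbols or none were named in no comparison. Where several probe sets shared a gene, the one with the highest mean over the 3 arrays was taken, which left 22180 genes.

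A difference between 2 arrays is the difference of their deposited log2 values. An expression floor was set at the median, over probe sets with 1 symbol, of the mean over the 3 arrays, which was 6.50. A gene was counted as at least 2-fold apart when the difference was at least 1 and the higher of the 2 arrays was at or above the floor. With 1 array per group there were no replicates, so no test was run and no p-value, SD between animals or confidence interval exists for any difference. The number of arrays limits the precision of every value. As a within-array measure of technical and isoform spread, the differences of 2 probe sets of one gene were compared over 271 genes with several probe sets at or above the floor.

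The samples, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. Named were, per comparison, the 12 genes with the largest positive and the 12 with the largest negative difference at or above the floor, leaving out predicted models, small RNAs and multicopy families. The caveolins and cavins were named in every comparison, as were up to 4 members of each described list with the largest differences in the direction of its median. Where a list median was 0, and where a list held large differences of both signs, its members with the largest differences were named, a choice made after their values were seen. In all, 25 pathway lists and 17 cell type lists were fixed. For each list the median difference of its measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart at or below the 2.5th or at or above the 97.5th percentile, where 1 random list in 20 would fall, and 4 of the 40 simulated lists described below did. The percentile describes these arrays only. Lists with fewer than 5 measured members were not described this way, which left out red blood cells, with 3 measured members, and mitochondrially encoded genes, with 0, so 40 lists were described.

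Many values were exactly equal between arrays, to within 1e-09. All 3 arrays had the same value in 41.4% of probe sets and in 43.2% of the 11510 genes at or above the floor, and at least 2 arrays had the same value in 75.3% of those genes. Many list medians were therefore exactly 0, and very small nonzero medians reached extreme percentiles, so the size of a median is given with it.

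Each comparison with AP control used the same array, so the correlation of both comparisons was set beside a simulation of 3 unchanged arrays of equal noise. Alternatives were centring each array on its median, quantile normalization, subtraction of a loess trend with a span of 0.3, the mean of all probe sets of a gene, other floors, thresholds of 1.5-fold and 3-fold, the list mean, only list members at or above the floor, and 10 bins. Omission of the lens list from the counts and of microglia markers from the complement list, and the correlation over genes under 2-fold in both comparisons, were added after the data were seen. The counting and the list percentiles were tested on simulated data. With 200 of 22180 genes changed at a noise SD of 0.15 per array, 38.0% of genes changed by a log2 difference of 1 and 98.0% of those changed by 1.5 were counted as at least 2-fold apart, as were 0 unchanged genes. The threshold of 1 lies far above that noise, which holds no spread between animals or pools. The 0 therefore gives no rate of false calls for these arrays. Of 40 simulated lists without a shift, at a noise SD of 0.2, 4 stood apart, and with a shift of 0.3 all 40 did. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.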

Results

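The study measured gene expression in mouse retina after intravitreal injection of agents related to caveolin-1, the main coat protein of caveolae in most cells. Cavtratin is a cell-permeable peptide that carries the scaffolding domain of caveolin-1, and Cav1-shRNA is a short hairpin RNA named for the Cav1 transcript. There were 3 arrays, for AP control at 2 hr, cavtratin at 2 hr and Cav1-shRNA at 2 days, each of 5 to 6 pooled retinae. There were no replicates, so every difference below compares 2 arrays and not the conditions. Array medians were 6.07 in AP control, 6.01 in Cav1-shRNA and 6.06 in cavtratin on the log2 scale. Pearson's r between arrays over all probe sets was lowest for AP control with cavtratin, at 0.9947, and highest for Cav1-shRNA with cavtratin, at 0.9954. At or above the floor of 6.50 were 11298 genes in AP control, 11362 in Cav1-shRNA and 11406 in cavtratin.

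The targeted gene came first. Cav1 had a value of 8.26 in all 3 arrays, with a difference of exactly 0, so no lower value was measured in the array labelled Cav1-shRNA. Cav2, which encodes the partner of caveolin-1 in caveolae, was at 8.75 in all 3 arrays. Cavin2 was at 6.25 and Cavin4 at 5.09 in all 3, both below the floor. Cavin1, a coat protein needed to form caveolae, was at 6.29 in AP control and at 6.44 in both other arrays. Cavin3 was at 7.93 in AP control and cavtratin and at 7.98 in Cav1-shRNA. Cav3, the muscle caveolin, was below the floor at 4.73, 4.76 and 4.51 in AP control, Cav1-shRNA and cavtratin. Over the 15 measured genes of the caveolae list the median difference from AP control was 0 in both comparisons, and none of the 15 was 2-fold apart. The largest difference in that list was that of Ehd1, an endocytic recycling protein, 0.69 higher in cavtratin. Each caveolin and cavin had 1 probe set, and since many values were exactly equal between arrays, the tie does not exclude a lower Cav1 level. All directions below that involve the array labelled Cav1-shRNA are drawn with no lower Cav1 value measured in it.

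**Figure D1:**
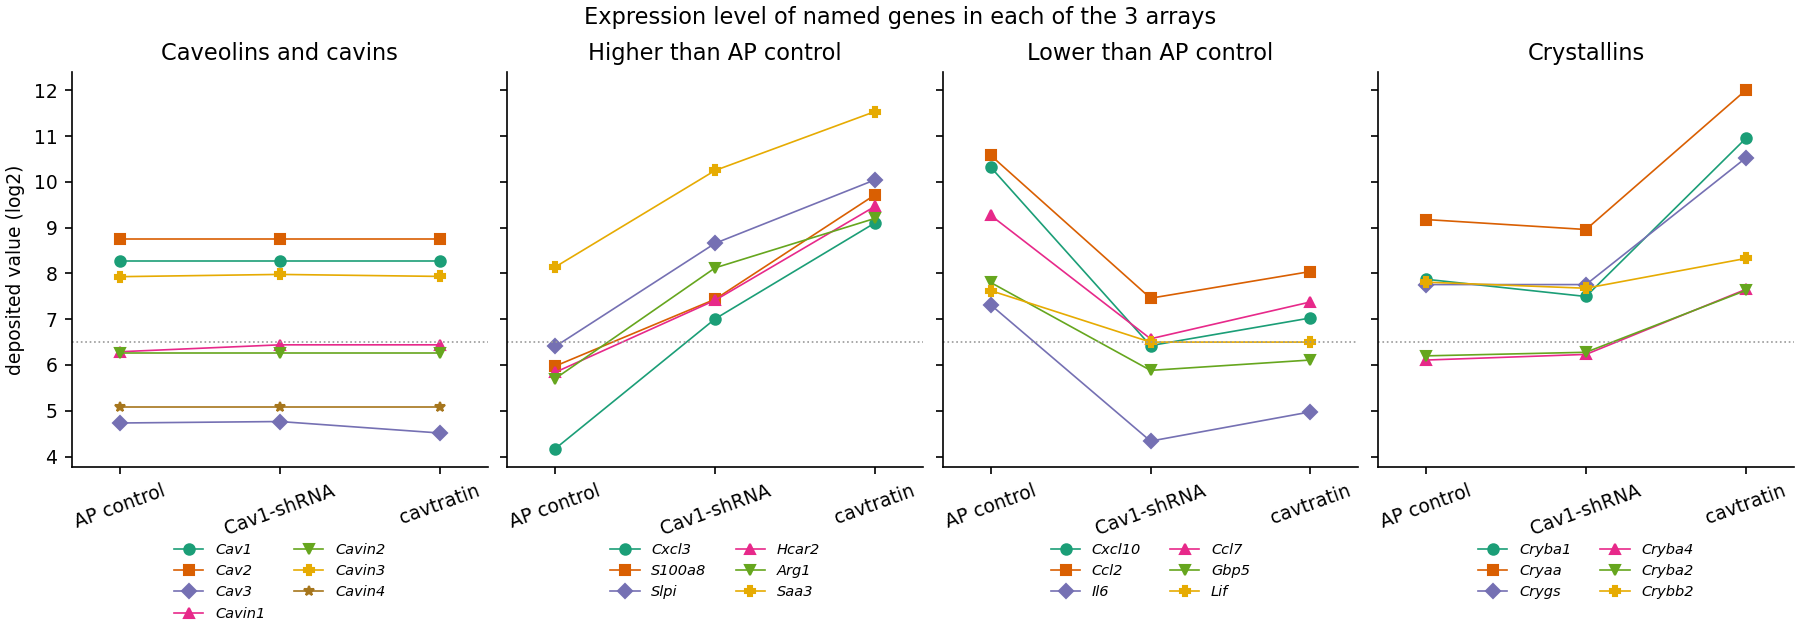
Deposited log2 values (vertical axis) of named genes in the 3 arrays (horizontal axis), 1 point per array and gene, with lines that only join the values of one gene and a dotted line at the floor of 6.50. Cav1 lies at 8.26 in all 3 arrays, Cxcl3 is at 4.17 in AP control, below the floor, and at 9.10 in cavtratin, Cxcl10 is at 10.32 in AP control and 6.42 in Cav1-shRNA, and Cryba1 is at 7.87 in AP control and 10.95 in cavtratin.

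Cavtratin was compared with AP control at the same time, 2 hr after injection. Lens markers, neutrophil and monocyte markers and microglia and macrophage markers were higher in the cavtratin array, with list medians of 0.52, 0.29 and 0.068. Over members at or above the floor alone these were 0.96 for 13 lens markers, 1.69 for 9 neutrophil and monocyte markers and 0.33 for 13 microglia and macrophage markers. Here and below, a member was kept when the higher of the 2 compared arrays reached the floor. That rule lets in members high in 1 array alone, so such medians depend on the differences themselves and are no firmer values. Of 11477 genes at or above the floor, 156 were at least 2-fold higher in cavtratin and 11 were at least 2-fold lower. Cxcl3, a neutrophil-attracting chemokine, was 4.93 higher on the log2 scale, S100a8, a calcium-binding protein abundant in neutrophils, 3.74, and Slpi, a secreted inhibitor of leukocyte proteases, 3.64. Hcar2, a receptor for hydroxycarboxylic acids, was higher by 3.62, Clec4e and Clec4d, myeloid C-type lectin receptors, by 3.54 and 3.22, and Il1f9, an interleukin-1 family cytokine, by 3.54. Arg1, the arginine-degrading enzyme arginase 1, was higher by 3.50, Ccrl2, a chemerin-binding receptor, by 3.49, Saa3, an acute-phase serum amyloid, by 3.39, and Stfa2l1, a stefin-like protease inhibitor, by 3.21. In 85 of the 156 genes the AP control value lay below the floor, among them all genes just named but Clec4e and Saa3, so their folds can be too small and their order was not read. The cavtratin value lay below it in 4 of the 11 lower genes, Il6, Gbp5, Ifi203-ps and Ptx3.

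The lower side was led by Cxcl10, an interferon-inducible chemokine, at −3.29, with 10.32 in AP control and 7.03 in cavtratin. Ccl2 and Ccl7, chemokines that attract monocytes, were at −2.54 and −1.89, and Il6, an acute-phase cytokine, was at −2.34. The interferon-inducible guanylate-binding protein genes Gbp5, Gbp9 and Gbp10 were at −1.69, −1.25 and −1.02, and the interferon-inducible pseudogene Ifi203-ps was at −1.34. Lif, a cytokine made by Muller glia in retinal injury, was at −1.12, Plat, tissue plasminogen activator, at −1.05, and Ptx3, a soluble pentraxin, at −1.01. Tnfaip6, a hyaluronan-binding protein, was at −0.98, short of 2-fold.

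By fixed lists, neutrophil and monocyte markers had a median of 0.29 and a mean of 0.87 over 16 measured genes, with the median at the 100th percentile of matched random lists. Of the 16, 12 lay above 0 and 3 below, the lowest being the monocyte marker Ly6c2 at −0.43. In that list 6 genes were at least 2-fold higher, among them Csf3r, the granulocyte colony-stimulating factor receptor, at 1.96, Retnlg at 1.95 and Mmp8, a neutrophil collagenase, at 1.86. Microglia and macrophage markers had a median of 0.068 and a mean of 0.68 over 17 genes, both at the 100th percentile. Of these, 6 genes were at least 2-fold higher, led by Cd14 at 2.64, Fcer1g at 1.85, Itgam at 1.68 and Mpeg1 at 1.64, while P2ry12, a receptor of resident microglia, was exactly equal in all 3 arrays at 6.87. The list of NF-kB targets, cytokines and chemokines held 9 genes at least 2-fold higher and 4 at least 2-fold lower among 31, with 15 above 0 and 14 below. Its median was 0, not apart, while its mean of 0.19 stood apart at the 99.8th percentile, and over its 22 members at or above the floor, 14 above 0 and 8 below, the median was 0.38 at the 100th percentile. Its higher members included Il1rn at 2.57, Il1a at 2.46, Ccl3 at 2.43 and Cxcl2 at 2.31, and its 4 lower members were Cxcl10, Ccl2, Il6 and Ccl7. Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, was 1.15 higher. Interferon-stimulated genes had a median of 0 over 27 genes, with 11 above 0, 11 below and 0 at least 2-fold apart.

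Crystallins, the structural proteins of the lens, were higher in the cavtratin array, and 7 of the 14 measured were at or above the floor in AP control too. The lens list had a median of 0.52 at the 100th percentile over 22 genes, and 6 were at least 2-fold higher: Cryba1 at 3.08, Cryaa at 2.83, Crygs at 2.77, Cryba4 at 1.54, Cryba2 at 1.43 and Cryab, which the retinal stress list holds too, at 1.09. The 8 lens genes in the list that are not crystallins had a median of 0, with 3 above 0, and 5 of the 8 lay below the floor in both arrays. Without the lens list, 150 genes were at least 2-fold higher and 11 lower, a count added after the data were seen.

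Genes of retinal neurons differed little. Median differences were −0.022 for rod photoreceptors, −0.027 for bipolar cells, −0.070 for retinal ganglion cells and −0.017 for synaptic transmission, each at or below the 2.5th percentile and each with 0 genes 2-fold apart. These lists had 0, 0, 0 and 1 members above 0, with 8, 9, 11 and 11 below. The oxidative stress list had a median of 0.097, or 0.15 over 13 members at or above the floor, and 1 gene at least 2-fold higher of 14, Hmox1, heme oxygenase 1, at 1.88. Immediate-early genes had a median of 0.056 over 26 genes, or 0.097 over the 19 at or above the floor, with Nr4a3 at 1.04, Dusp1 at 0.88 and Nr4a1 at 0.63. Among 17 hypoxia and glycolysis genes with a median of 0.0079, or 0.017 over 15 at or above the floor, Egln3, an oxygen-sensing prolyl hydroxylase, was at 2.06 and Pfkfb3, a glycolytic regulator, at 1.38. The list of nitric oxide, cyclic GMP and caveolin-1 partner genes had a median of 0 over 17 and a mean of 0.36 that stood apart at the 99.9th percentile, with 3 genes at least 2-fold higher, Nos2, inducible nitric oxide synthase, at 2.19, Ednrb, an endothelin receptor, at 2.07, and Hmox1. Angiogenesis genes also had a median of 0, over 20, and their mean of 0.23 stood apart at the 99.6th percentile, with Thbs1, thrombospondin 1, at 2.99 as the 1 gene at least 2-fold higher. Cone photoreceptors had a median of −0.0049, not apart, and a mean of −0.060 at the 1.07th percentile. In all, 13 of 40 lists stood apart by the median, against 4 of 40 simulated lists without a shift. That simulation used a noise SD of 0.2, while 54.5% of genes at or above the floor had a difference of exactly 0 here. Its 4 of 40 therefore need not be the chance rate of these arrays, here or in the comparisons below. Of the 13, 2 had a median of at least 0.1 in size and 11 lay between −0.070 and 0.097. The other 27 had medians between −0.0049 and 0. In 6 of the 13 another scaling moved the median by over 1.5 times with its sign kept, among them synaptic transmission and bipolar cells, at −0.039 and −0.041 after quantile normalization, and hypoxia and glycolysis, at 0.015 after centring.

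The array labelled Cav1-shRNA, taken 2 days after injection, was compared with AP control, taken at 2 hr. Microglia and macrophage markers and neutrophil and monocyte markers were higher here too, with list medians of 0.42 and 0.24. Interferon-stimulated genes and NF-kB targets, cytokines and chemokines were lower, with list medians of −0.11 and −0.10. Of 11433 genes at or above the floor, 39 were at least 2-fold higher and 14 were at least 2-fold lower. Cxcl3 was higher by 2.84, Arg1 by 2.42, Slpi by 2.25, Saa3 by 2.11 and Ccrl2 by 2.02. Clec4d was higher by 1.96, Il1f9 by 1.89, Clec4e by 1.77 and Hcar2 by 1.57. Cd53, a leukocyte tetraspanin, was higher by 1.63, Tnfrsf1b, a tumor necrosis factor receptor, by 1.52, and Ly6c2, a surface marker of inflammatory monocytes, by 1.49. On the lower side Cxcl10 was at −3.90, Ccl2 at −3.12, Il6 at −2.98, Ccl7 at −2.70, Gbp5 at −1.92 and Ifi203-ps at −1.59. Grem1, a secreted BMP antagonist, was at −1.31, Serpinb2, a plasminogen activator inhibitor, at −1.23, Cxcl1, a neutrophil-attracting chemokine, at −1.19, Lif at −1.12, Car13, a carbonic anhydrase, at −1.10 and Ifi205 at −1.08.

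Microglia and macrophage markers had a median of 0.42 over 17 genes at the 100th percentile, with 16 of 17 above 0. Mpeg1 at 1.21, Fcer1g at 1.09 and Cd68 at 1.07 were at least 2-fold higher, and Ctss, a lysosomal cathepsin, was at 0.87. Neutrophil and monocyte markers had a median of 0.24 over 16, with Ly6c2 and S100a8, at 1.46, at least 2-fold higher, and 0.84 over the 5 at or above the floor. Antigen presentation genes had a median of 0.19 over 15, with 0 at least 2-fold apart, and H2-Aa at 0.69 and H2-Eb1 at 0.60, class II genes, had the largest differences. Complement genes had a median of 0.14 over 15, also with 0 at least 2-fold apart, with C3ar1 at 0.73, C5ar1, below the floor in both arrays, at 0.56 and C1qa at 0.45. Of these 15 complement genes 9 lay above 0 and 2 below, with Cfb, complement factor B, lowest at −0.69. The microglia list holds 3 of the 15 too, C1qa, C1qb at 0.42 and C1qc at 0.17, and the other 12 had a median of 0.057, a value added after the data were seen. The list of NF-kB targets, cytokines and chemokines had a median of −0.10 and a mean of −0.49 over 31, and a median of −0.16 over the 21 at or above the floor, with 5 genes at least 2-fold lower and 1, Il1rn at 1.25, at least 2-fold higher. Interferon-stimulated genes had a median of −0.11 over 27, at the 0th percentile, with Rsad2 at −1.01, Ifit1 at −0.81 and Gbp3 at −0.69. Vascular endothelium markers had a median of 0.041 over 18, or 0.19 over the 13 at or above the floor, with 11 above 0 and 0 below, led by Cdh5, the endothelial cadherin, at 0.53 and Emcn at 0.43, and Muller glia markers had a median of 0.050 over 14. Rod, cone, amacrine and ganglion cell markers had medians of 0. The lens list had a median of 0, a mean of −0.085 at the 0.77th percentile, and a median of −0.030 over its 10 members at or above the floor. The list of nitric oxide, cyclic GMP and caveolin-1 partner genes and that of angiogenesis also had medians of 0, while their means of 0.19 and 0.13 stood apart, with Hmox1 at 1.28 and Thbs1 at 1.20.

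Of 40 lists, 16 stood apart by the median, again against 4 in simulation, 6 of the 16 with a median of at least 0.1 in size and 10 between −0.023 and 0.053, and the other 24 had a median of 0. The list of p53 targets and apoptosis had a median of 0.010 and a mean of −0.037, and with members at or above the floor alone it did not stand apart. The 3 that changed sign in at least 1 other scaling, cholesterol synthesis and uptake, synaptic transmission and bipolar cells, had medians of −0.023, −0.0037 and −0.0032, with −0.0068 for synaptic transmission over members at or above the floor. In 9 more the median moved by over 1.5 times with its sign kept, and centring gave −0.054 for interferon-stimulated genes, −0.043 for NF-kB targets, cytokines and chemokines, 0.099 for vascular endothelium and 0.11 for Muller glia. Centring adds 0.058 to every gene of this comparison. This comparison joins the hairpin to a later time, 2 days against 2 hr, and to another kind of agent, and the array design cannot separate them. In 21 of the 39 higher genes, Cxcl3, Arg1, Slpi, Ccrl2, Clec4d, Il1f9, Hcar2 and S100a8 among them, the AP control value lay below the floor, as did the Cav1-shRNA value in 9 of the 14 lower genes, with Cxcl10, Il6, Gbp5, Ifi203-ps, Grem1, Serpinb2, Cxcl1 and Car13, so folds can be too small there.

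Both comparisons share the AP control array, and their differences were set against each other over 11510 genes. Of the 39 genes higher in the array labelled Cav1-shRNA, 37 were also at least 2-fold higher in cavtratin, and of the 14 lower genes 7 were lower in both. Independent lists of those sizes would share 0.529 and 0.0134 genes, which leaves out the shared array. In all 37 shared higher genes the Cav1-shRNA value lay between AP control and cavtratin. Of the 7 shared lower genes, 4 lay below the floor in Cav1-shRNA or cavtratin, so their order between these arrays was not read. Pearson's r across genes was 0.746 and Spearman's rho 0.533, with genes that are not independent replicates, and a shared control alone gave r = 0.499 in simulated unchanged arrays. The covariance was 0.0317, against 0.0058 in that simulation at a noise SD of 0.076 per array, taken from the spread between probe sets of one gene and without any spread between animals. Part or all of the excess may come from the shared array, which cannot be split. The simulation gave every array equal noise, and a larger deviation of the AP control array alone would raise both r and the covariance. Without genes 2-fold apart in either comparison, r was 0.582. The 1 gene apart in opposite directions was Serpinb2, 1.10 higher in cavtratin and at −1.23 in Cav1-shRNA.

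**Figure D2:**
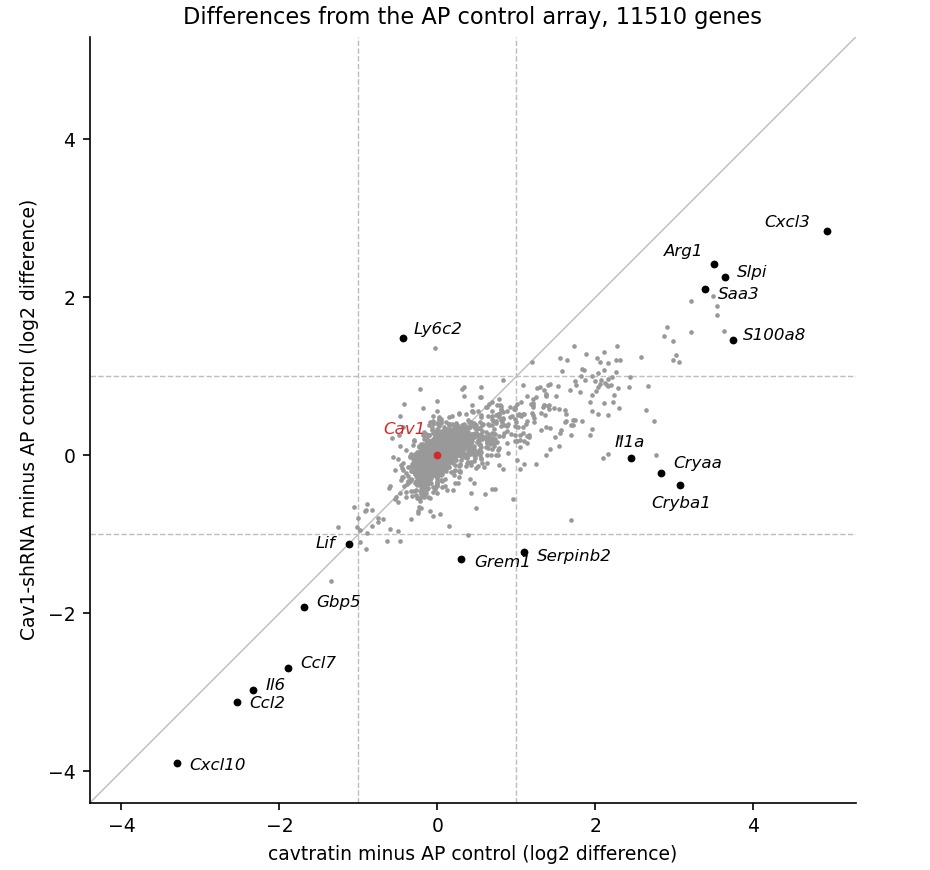
Each point is 1 of 11510 genes at or above the floor, with the log2 difference cavtratin minus AP control on the horizontal axis and Cav1-shRNA minus AP control on the vertical axis, dashed lines at a difference of 1 in size and a solid line of equality. Cxcl3 lies at 4.93 and 2.84 and Cxcl10 at −3.29 and −3.90, Cryba1 at 3.08 is at −0.38 in Cav1-shRNA, and Cav1 lies at 0 on both axes.

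The array labelled Cav1-shRNA was also set against cavtratin directly, a comparison that does not use AP control. Lens markers, NF-kB targets, cytokines and chemokines, and neutrophil and monocyte markers were lower in Cav1-shRNA, and antigen presentation genes were higher, by the list medians given after the single genes. Of 11472 genes at or above the floor, 4 were at least 2-fold higher in Cav1-shRNA and 90 were at least 2-fold lower, and in 29 of the 90, Serpinb2 and Ccl4 among them, the Cav1-shRNA value lay below the floor. The 4 higher genes were Ly6c2 at 1.92, Ms4a7, a macrophage membrane protein, at 1.39, Ccl5, a T cell-attracting chemokine, at 1.08, and Ecel1, a neuronal endopeptidase induced by nerve injury, at 1.06, with the cavtratin value of Ly6c2 and Ms4a7 below the floor. Next, under 2-fold, were Sprr1a, a gene induced in injured neurons, at 0.97, Apod at 0.79, H2-Eb1 at 0.78, H2-Aa at 0.69, Trem2, a microglial receptor, at 0.57, Apobec2 at 0.55, Crispld2 at 0.54 and Ctss at 0.53. The lower side was led by Cryba1 at −3.45, Cryaa at −3.04 and Crygs at −2.77. Ptgs2, the inducible cyclooxygenase, was at −2.50, Il1a at −2.49, Serpinb2 at −2.33, Slfn4 at −2.31, S100a8 at −2.28, Ccl4 at −2.15, Il1b at −2.13, Cxcl3 at −2.10 and Cxcl2 at −2.09.

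By list, the lens had a median of −0.655 over 22 genes with 6 at least 2-fold lower, and NF-kB targets, cytokines and chemokines a median of −0.48 over 31, with 9 at least 2-fold lower and 1 higher, Ccl5. Neutrophil and monocyte markers had a median of −0.21, with 5 of 16 at least 2-fold lower and 1, Ly6c2, higher. Over members at or above the floor these medians were −0.85 for 20 NF-kB targets, cytokines and chemokines and −1.26 for 9 neutrophil and monocyte markers. Retinal pigment epithelium markers had a median of −0.17 over 15, with 0 at least 2-fold apart and Rgr at −0.40 and Dct at −0.32, and their mean of −0.12 at the 2.68th percentile did not stand apart. Antigen presentation had a median of 0.092, complement 0.067 and Muller glia 0.063, with 0 genes at least 2-fold apart in each, and the 12 complement genes outside the microglia list had a median of 0.013, a value added after the data were seen. Microglia and macrophage markers had a median of 0 with a mean of −0.19 at the 0.49th percentile, with Cd14 at −2.06 and C1qb at 0.51, and a median of −0.016 over 13 at or above the floor. Of other lists with medians of 0, means stood apart at −0.16 for nitric oxide, cyclic GMP and caveolin-1 partner genes, −0.13 for hypoxia and glycolysis, 0.076 for vascular endothelium and 0.048 for retinal ganglion cells, as did one of 0.046 for cone photoreceptors at a median of 0.0019. In all, 13 of 40 lists stood apart by the median, against the same 4 in simulation, 4 of the 13 with a median of at least 0.1 in size, and the other 27 had medians between 0 and 0.0040. The medians of retinal stress and gliosis, −0.016, and of oxidative stress, −0.012, changed sign when each array was centred on its median. Immediate-early genes had a median of −0.078 and interferon-stimulated genes one of −0.064. In 7 lists the median moved by over 1.5 times with its sign kept, and centring gave −0.027 for immediate-early genes, −0.013 for interferon-stimulated genes, 0.14 for antigen presentation, 0.12 for complement and 0.11 for Muller glia. Centring adds 0.051 to every gene of this comparison, those of the random lists included. Over members at or above the floor the medians were −0.17 for immediate-early genes, −0.14 for interferon-stimulated genes, 0.15 for antigen presentation, 0.20 for complement and −0.024 for oxidative stress. Without the lens list, 84 genes were at least 2-fold lower and 4 higher, a count added after the data were seen. As in the comparison with AP control, the hairpin cannot be separated from time and agent.

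**Figure D3:**
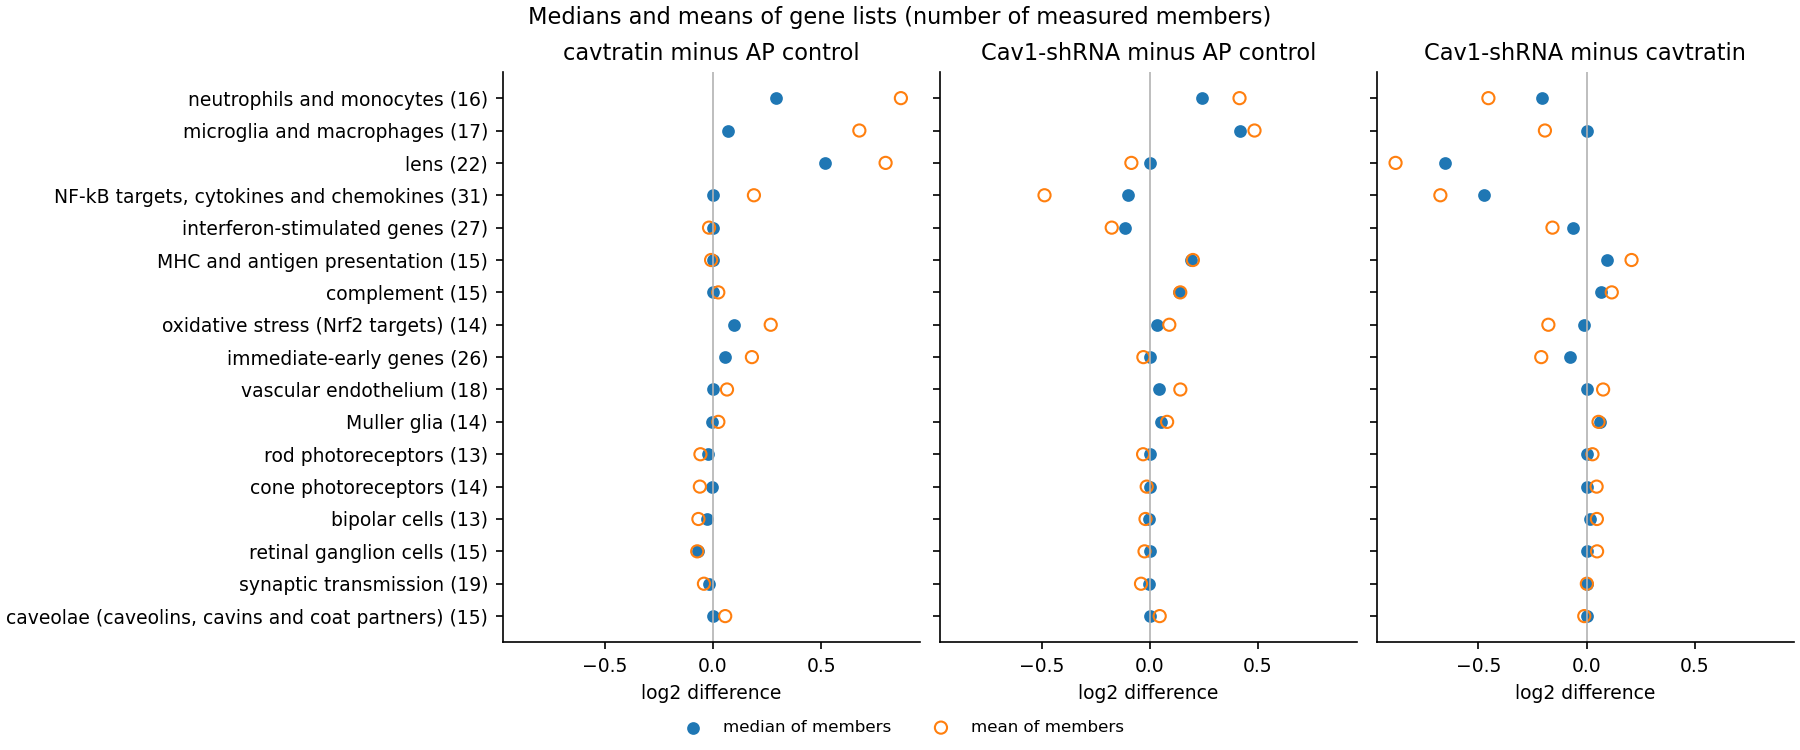
Median (filled) and mean (open) log2 difference of the measured members of 17 gene lists on the horizontal axis, 1 panel per comparison, with the number of measured members after each name. Lens markers lie at a median of 0.52 for cavtratin minus AP control and 0 for Cav1-shRNA minus AP control, while the neuronal lists lie within 0.1 of 0 in every panel.

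Treating the 3 arrays alike, 30 genes were at least 2-fold higher in cavtratin than in both other arrays while these lay within 0.5 of each other, and 0 were lower. They included the crystallins Cryba1, Cryaa, Crygs, Cryba4 and Cryba2, and Il1a, Il1b, Ccl4, Cxcl2 and Slfn4. AP control stood apart in 7 genes, higher in Gbp5, Ifi203-ps and Lif and lower in Tgfbi, Clec4n, Mpeg1 and Slamf7. The array labelled Cav1-shRNA stood apart in 4 genes, higher in Ly6c2 and Ms4a7 and lower in Grem1 and Rsad2. Clec4n and Slamf7 were named after their values were seen. The spread between 2 probe sets of one gene was 0.119 for cavtratin minus AP control, 0.0904 for Cav1-shRNA minus AP control and 0.112 for Cav1-shRNA minus cavtratin, as an SD on the log2 scale over 271 genes, and it holds no spread between animals.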

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

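The tests of a lower neuronal share, of the AP control array standing alone and of ties at high levels were chosen only after the results were seen, as was the condition that lens genes below the floor decide nothing.

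Probe sets without a single gene name took no part in the report's comparisons, and 17824 were measured. Of these, 30 were at least 2-fold higher in cavtratin than in AP control and 20 were at least 2-fold lower. In the array labelled Cav1-shRNA, 6 were at least 2-fold higher than in AP control and 73 were at least 2-fold lower, while among named genes 39 were higher and 14 lower.

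Crystallins were higher in cavtratin than in AP control, with a median difference of 0.97 over 14 genes, against −0.059 in Cav1-shRNA minus AP control. A loss of RNA from retinal neurons that raises everything else would have to raise other non-neuronal markers alike. Over 70 markers of 5 such cell types the mean was 0.078, with an SD of 0.185. Their median of 0 decides little, since 54.5% of genes at or above the floor had a difference of exactly 0. Over members at or above the floor, vascular endothelium had a median of 0.061 and retinal pigment epithelium one of 0.056. Pericytes and smooth muscle had 0 and Muller glia −0.0033. These values argue against a rise of the crystallin size from that source, but not against a small one. Lens tissue in the pooled retinae cannot be told apart from expression in the retina: the 8 lens genes that are not crystallins had a median of 0, which met the bound set in advance against lens tissue without passing it, but 5 of the 8 lay below the floor in both arrays and 3 were above 0. Cryaa reached 12.00 and Crygs 10.52, while Mip, a membrane protein of lens fibre cells, was at 6.80 in AP control and 6.74 in cavtratin, Hsf4 was at 6.72 in both, Grifin, a galectin-like lens protein, was at 7.18 and 7.92, Bfsp1 was 0.52 higher in cavtratin below the floor, and 1 of the 22 lens genes, Cryab, is in the retinal stress list too. An effect of cavtratin itself stays open and was not tested, since 1 pool of retinae carries the whole pattern.

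Of the genes at least 2-fold from AP control in both comparisons, 37 were higher and 7 lower, which a single deviating AP control array could give. For the 37 higher genes the median size of the difference between Cav1-shRNA and cavtratin was 1.08, and the signed differences had quartiles of −1.48 and −0.80. The difference between Cav1-shRNA and cavtratin holds no AP control value, so no deviation of the AP control array could produce it. Its size shows only that these 2 arrays differ in these genes, and it does not test the AP control array. It cannot be told whether a low AP control array gives the part that both comparisons share, since a further rise in cavtratin would leave the same values. For the 7 lower genes, with Cxcl10, Ccl2, Il6 and Ccl7 among them, that median size was 0.58, but 4 of the 7 lay below the floor in Cav1-shRNA or cavtratin, so a high AP control array cannot be told apart from lower levels in both other arrays. AP control and cavtratin were both taken 2 hr after injection, so time after injection cannot give the differences between those 2 arrays. For Cav1-shRNA the design confounds time with the agent. Injection injury and the agents stay open as biological differences in both comparisons.

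Exact ties between arrays included well-expressed genes, among them Cav1 at 8.26 and Gapdh at 12.59. A constant filled in for low values would leave high genes untied, and 43.2% of genes at or above the floor were equal on all 3 arrays. Median polish, a summary of probes that takes medians over arrays, made 79.2% of simulated probe sets of 25 probes equal on all 3 arrays, 88.9% at 40 probes, 56.9% at 15 and 17.4% at 10, against 41.4% observed and 0% when 4 arrays were simulated, so it may be the source. Different probe sets also shared values: the 17113 tied probe sets held 5637 distinct values, and 23.3% of them had a value found once. The simulation was scored on ties between arrays only, so it does not speak to this sharing. In a simulation of that summary, a true log2 difference in 1 array could still leave all 3 arrays equal, as they are for Cav1. At assumed probe noise SDs of 0.3, 0.5 and 1, a difference of −0.25 did so in 13.2%, 43.2% and 67.4% of probe sets. For −0.5 the shares were 0%, 5.025% and 43.2%, and for −1 they were 0%, 0% and 5.025%. At −1 and an SD of 1 the median reported difference was −0.50. A lower Cav1 level hidden by the summary therefore stays open, no biological explanation was tested, and the number of probes, their noise and the authors' summary method are not given in the sources used here.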

How the results depend on the processing

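The omission of the lens list, and of genes 2-fold apart from the correlation and of microglia markers from the complement list, was chosen only after the data were seen. No paired analysis was possible because there was 1 array per group. Signal over background limits the counts, since a value below the floor can make a fold too small.

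Under 3 other scalings and the mean of probe sets, at least 154 of the 156 higher and 10 of the 11 lower genes of cavtratin minus AP control kept their 2-fold call. All 39 higher and at least 13 of the 14 lower genes of Cav1-shRNA minus AP control did, as did all 4 higher and at least 85 of the 90 lower genes of Cav1-shRNA minus cavtratin. The median of all genes shifted by at most 0.058, and Cav1 moved by less than the spread between probe sets. With shifts this small few calls could change, so the kept calls are no measure of the spread between pools. Among named genes 287 alternative values moved by less than that spread and 1 by more, as Cryaa in Cav1-shRNA minus cavtratin was at −2.20 with the mean of probe sets. Of the lists that stood apart, 10 of 13 in cavtratin minus AP control kept their call and direction by the mean and 12 by quantile normalization. In Cav1-shRNA minus AP control 12 of 16 did by either and 13 after centring, and in Cav1-shRNA minus cavtratin 11 of 13 did after centring or quantile normalization and 12 by the mean. With a 1.5-fold threshold, higher and lower counts were 251 and 27, 103 and 42, and 11 and 175 in the same order of comparisons. With 3-fold they were 86 and 5, 9 and 6, and 1 and 26. With the floor at the 75th percentile, which counts fewer genes, they were 81 and 5, 16 and 5, and 2 and 54. The spread between probe sets of cavtratin minus AP control was 0.0725 with that floor, and the cause was not tested.

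For genes in which 1 array stands apart, that floor gave 0 higher and 2 lower in AP control, 0 higher and 1 lower in Cav1-shRNA, and 12 higher in cavtratin. The 1.5-fold threshold, with the other arrays within 0.3, gave 17 and 12 in AP control and 4 and 4 in Cav1-shRNA. Centring and quantile normalization each left 1 lower gene in Cav1-shRNA, and the cause was not tested. The correlation of both comparisons was 0.582 over genes under 2-fold in both, which takes out the largest differences by construction. Of lists for cavtratin minus AP control, 21 stood apart with members at or above the floor only, against 13, and the cause was not tested. The complement list without the 3 genes that the microglia list holds too had medians of 0.057 in Cav1-shRNA minus AP control and 0.013 in Cav1-shRNA minus cavtratin, and both stood apart.

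These lists changed sign. Centring adds 1 offset to every gene, 0.058 in Cav1-shRNA minus AP control and 0.051 in Cav1-shRNA minus cavtratin. These offsets are larger than the negative medians concerned, which accounts for the sign changes after centring. The cause of the other changes was not tested. In Cav1-shRNA minus AP control, centring gave 0.035 for cholesterol synthesis and uptake, 0.054 for synaptic transmission and 0.055 for bipolar cells, quantile normalization gave 0.0057 for cholesterol and 0.0043 for bipolar cells, and the mean gave −0.037 for p53 targets and apoptosis. In Cav1-shRNA minus cavtratin, centring gave 0.035 for retinal stress and gliosis and 0.039 for oxidative stress, and quantile normalization gave 0.011 for the latter.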

Other observations

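In several gene groups outside the main account, single members differed between arrays while the list median stayed near 0. In the retinal stress list, whose median was 0.019 in cavtratin and 0 in Cav1-shRNA over 23 genes, Cebpb was 0.71 and Socs3 0.55 above AP control in cavtratin, and Gfap, the glial intermediate filament gene, was 0.37 above it in cavtratin and 0.36 in Cav1-shRNA. Steap4 in the same list was at −0.60 and −0.93. Among TGF-beta targets, with medians of 0.011 and 0 over 16 genes, Tgfbi was 1.73 and 1.38 above AP control. Among 18 junction genes of the blood-retina barrier, with a median of 0 in both, Cldn1 was 1.14 higher in cavtratin while Cldn5, the main endothelial claudin, was at −0.17. In the heat shock list, with a median of 0, Hspa1b was at 0.66 and Hspa1a at 0.46 in cavtratin.

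In the array labelled Cav1-shRNA, Slc7a11, the cystine transporter, was at −0.89 against AP control while Hmox1, another gene of the oxidative stress list, was at 1.28, and the list median was 0.033. Fas, a death receptor, was at −0.76 in the p53 list, whose median was 0.010 and whose mean was −0.037. Pericyte and smooth muscle markers had a median of 0.053 over 13 genes in the same comparison. Among the 30 genes that stood apart in cavtratin, outside the naming rule and chosen after their values were seen, Nlrp3, an inflammasome sensor, was at 7.99 against 6.07 in AP control and 6.33 in Cav1-shRNA. Circadian clock, cell cycle, unfolded protein response and extracellular matrix lists had medians of 0 in all 3 comparisons, as did the lists of T cells, astrocytes, glucocorticoid-responsive genes and the epithelium of cornea, iris and ciliary body. The means of 2 of these stood apart: T cells at 0.12 in Cav1-shRNA minus AP control, with all 10 members below the floor, and the epithelium at 0.10 in Cav1-shRNA minus AP control and 0.083 in Cav1-shRNA minus cavtratin, with 4 of 13 members at or above the floor. Cytosolic ribosomal proteins had medians of 0, 0.0079 and 0 in cavtratin minus AP control, Cav1-shRNA minus AP control and Cav1-shRNA minus cavtratin, and nuclear oxidative phosphorylation genes had medians of 0, 0 and 0.024. Where these medians were not 0, centring or quantile normalization moved them by over 1.5 times with the sign kept: quantile normalization gave 0.0081 for retinal stress in cavtratin, and centring gave 0.018 for TGF-beta targets in cavtratin. In Cav1-shRNA minus AP control centring gave 0.091 for oxidative stress, 0.069 for p53 targets, 0.11 for pericytes and 0.066 for ribosomal proteins, and in Cav1-shRNA minus cavtratin 0.075 for oxidative phosphorylation. Over members at or above the floor alone, Cav1-shRNA minus AP control gave 0.065 for oxidative stress, 0.020 for ribosomal proteins and 0.040 for extracellular matrix, and cavtratin minus AP control gave 0.020 for the unfolded protein response and −0.0043 for circadian clock genes, while Cav1-shRNA minus cavtratin gave 0.021 for glucocorticoid-responsive genes. The members named here were chosen after their values were seen, and no explanation was tested for them.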
